A study of Stipitochalara longipes with 7 samples.

How the data were processed

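RNA was sequenced from 7 needle microcosms colonised by the ascomycete fungus Stipitochalara longipes, which the labels also call Chalara longipesis. Per the labels' protocols, each microcosm held 85 g of sand and 11 g of dry Scots pine needles, was sterilised by gamma radiation, received an ammonium chloride solution (20 ml at 100 mM) and was kept at 20 °C. The fungus was introduced on needles that it had already colonised for 2 months. Total RNA was isolated from 800 mg of frozen, ground material with a soil RNA kit, and paired reads of 125 bp were obtained on an Illumina HiSeq instrument, per the labels. The labels call the libraries of one harvest biological replicates, and there were 2 at 2 months, 2 at 5 months and 3 at 10 months. The protocols give 12 microcosms per species and 4 harvested at each time, so not every harvested microcosm has a library here.

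The authors deposited 1 table per library, each with the same 19765 gene models under their JGI (Joint Genome Institute) protein identifiers. Per the file headers, each table gives counts of unique gene reads, counts of total gene reads and an RPKM value. The aligner, the counter, the genome build and the annotation are not given in the sources used here, and no filter on the reads is stated. The RPKM values deposited by the authors divide the total gene reads by the length of the gene model and by the sum of total gene reads of the same library. This was tested on the files: the lengths that the RPKM and count columns imply differed between libraries by at most 0.0045 bp. Because RPKM scales every library to its own total, a few very abundant gene models lower the RPKM of all others, so RPKM was used only to recover the length. Implied lengths ran from 150 to 23924 bp with a median of 1323 bp over the 18407 gene models that had at least 1 read in any library.

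No source used here pairs the protein identifiers with gene names, products or positions. The 26 functional gene lists fixed before the data were examined (plant cell wall enzymes, oxidoreductases, nitrogen uptake, ribosomal proteins and others) therefore matched 0 gene models and were not tested, and no reference genome was used. Gene models are given by identifier and implied length only. Antisense or overlapping models cannot be told apart from these tables, and strand handling is not given in the sources used here.

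Total gene reads were the main measurement. Gene models were kept with filterByExpr at its default settings (14753 models), libraries were scaled by TMM, and one quasi-likelihood model with the 3 harvests as groups was fitted in edgeR 4.0.16 (R 4.3.3). The 3 pairwise comparisons and an F test for any difference among the harvests came from this fit, with Benjamini-Hochberg adjusted p under 0.05 and no fold minimum. All 7 libraries shared one estimate of the spread, because the 2-month and 5-month groups had 2 libraries each. Standard errors of log2 fold changes are the fold change divided by the square root of the quasi-likelihood F. CPM values are relative to the TMM-scaled library size. Gene models to be named were chosen by a rule fixed before the data were examined. For a series without gene names it takes the 2 largest rises and the 2 largest falls of each comparison. They were taken among gene models past the threshold, with a mean of at least 20 CPM in the higher group and no overlap between the libraries of both groups. The 8 most abundant gene models were singled out after their values were seen, as those with a mean of at least 1% of the reads.

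Library totals ran from 20009777 to 52554481 total gene reads. Outside the 8 most abundant gene models they ran from 2938002 to 16923473, and that number sets the precision for all other models. A count of 0 allows up to 3 reads, which is 1.02 CPM of such reads in the library with the fewest and 0.177 CPM in the one with the most. Such limits, and the 95% Wilson intervals on shares, cover counting error only, and reads without molecular identifiers are not independent molecules. To compare libraries at equal depth, reads outside the 8 models were thinned to 2938002 per library in 20 random draws (numpy 2.4.6).

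The test was tested on simulated data drawn from the means, TMM-scaled library sizes and dispersions of the real libraries, with 200 gene models changed. The changed models were drawn from the more abundant ones only. Each unchanged gene model kept the same mean share and the same dispersion in every library. Differences between the real libraries in spread, or in the joint share of the 8 abundant models, were not simulated, so the rates below may not hold for the real data. In the simulated 10 against 2 month comparison (13037 gene models tested), 25.4% of the 4-fold, 64.3% of the 8-fold and 73.1% of the 16-fold changes were called. In the simulated 5 against 2 month comparison (13491 tested) these shares were 16.7%, 47.8% and 64.6%. In the simulated 10 against 5 month comparison (13342 tested) they were 28.6%, 66.7% and 79.5%. Of the calls, 8 of 118, 3 of 89 and 4 of 120 were on unchanged gene models, in the same order.

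Replicate numbers are shared between harvests in the titles, and whether they pair the libraries was checked from the deviations from the harvest means. Same-numbered libraries did not deviate together, but with 2 libraries per harvest the deviations mirror each other, so this check is weak. The main model was fixed in advance without a replicate block. The alternatives fixed in advance were other scalings, DESeq2 1.42.0, other filters on low counts, a fold minimum, a replicate block, fits on 2 harvests only and leaving out each library in turn. Added after seeing the data were unique reads, halved counts, leaving out the 8 most abundant models, a covariate for their share, limma-voom with quality weights (limma 3.58.1) and leaving out the libraries with the fewest gene models detected at 2 and at 10 months. Figures were drawn with matplotlib 3.10.9.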

Results

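The transcriptome of Stipitochalara longipes, an ascomycete that decomposes pine needle litter, was profiled while the fungus grew as the single inoculated species on sterilised Scots pine needles. RNA was taken after 2 months (2 libraries), 5 months (2 libraries) and 10 months (3 libraries), and the design compares gene expression among these harvests. Total gene reads were 32062885 and 43955094 in 2-month replicates 1 and 2, and 52554481 and 20009777 in 5-month replicates 1 and 2. The 10-month replicates 1, 2 and 3 had 23125772, 29762444 and 39368275. Of the 19765 gene models, 18407 had at least 1 read in some library and 8859 had reads in every library, while 1358 had none. Results are given by JGI protein identifier, because the files do not pair the identifiers with names or functions.

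A small set of gene models held a large and variable part of every library. The 8 most abundant gene models, singled out after their values were seen, took 47.2% and 93.3% of the reads in the 2-month libraries. They took 86.9% and 30.0% in the 5-month libraries and 34.1%, 51.6% and 71.2% in the 10-month libraries. The mean share was 70.2% ± 32.6 (SD, n = 2) at 2 months, 58.5% ± 40.2 (SD, n = 2) at 5 months and 52.3% ± 18.6 (SD, n = 3) at 10 months, so libraries of one harvest differed by more than the harvest means did. Counting error was negligible beside this, with a 95% Wilson interval of 93.31% to 93.32% for 2-month replicate 2. Gene model 391853 (1039 bp) was the most abundant, with a mean of 20.4% of the reads and a range of 14.4% to 28.4%. Gene model 358623 (426 bp) varied most of the 8 against all other reads, from 2.4 to 390.7 reads per 100 reads outside the 8 models. Gene model 348936 (861 bp) behaved differently from the other 7 in that it took most in 2-month replicate 1 (3.2%) and least in 5-month replicate 1 (0.16%). At least 97.8% of the reads on each of the 8 models were unique. The tables hold no sequence or annotation, so reads of ribosomal RNA placed on these models are not told apart from messenger RNA, and the shares are not to be read as gene expression alone. With the 8 set aside, 16923473 and 2938002 reads remained for all other gene models at 2 months, 6880842 and 14010114 at 5 months, and 15234169, 14405478 and 11345883 at 10 months.

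**Figure D1:**
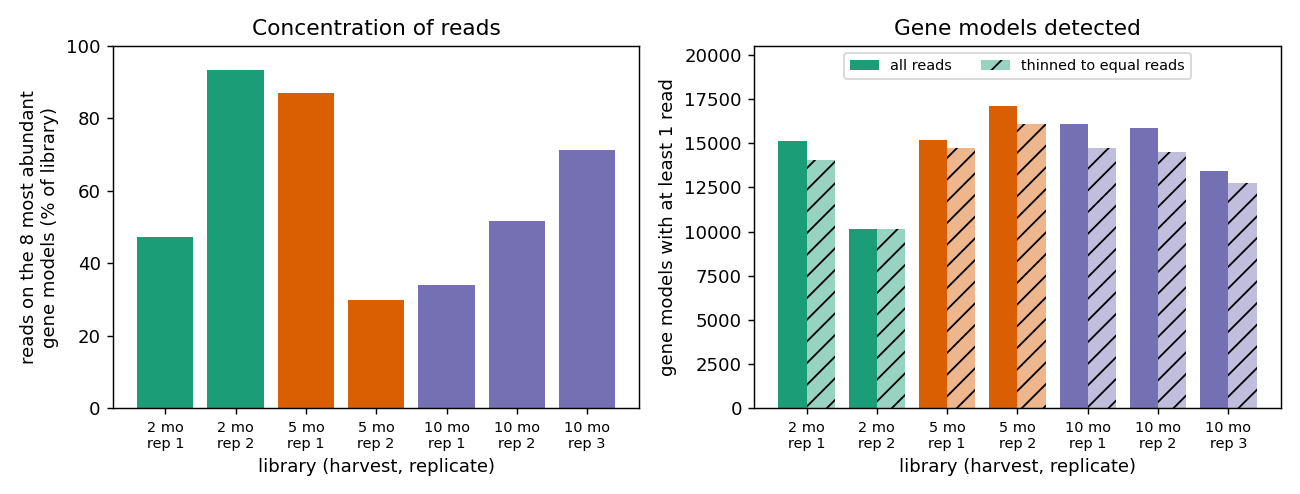
Left, percent of each library's reads on the 8 most abundant gene models; right, number of gene models with at least 1 read, from all reads (solid) and, for models outside those 8, after thinning to 2938002 reads (hatched). Each bar is 1 library, coloured by harvest; the share runs from 30.0% to 93.3% and 2-month replicate 2 has the fewest gene models detected (10139).

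The number of gene models detected also varied within harvests. It was 15115 and 10139 at 2 months, 15159 and 17076 at 5 months, and 16075, 15846 and 13405 at 10 months. After thinning to equal numbers of reads outside the 8 abundant models, 2-month replicate 2 still had the fewest with 10131, followed by 10-month replicate 3 with 12760, and the other 5 libraries had 14053 to 16097. Across all tested genes, the mean Spearman correlation of log2 CPM was 0.918 between libraries of one harvest (5 pairs) and 0.854 between harvests (16 pairs). The pair at 5 months correlated at 0.955 and the 10-month pairs at 0.924 to 0.972, whereas the 2-month pair correlated at 0.806. That is below the correlation of 2-month replicate 1 with each of the 5 later libraries (0.856 to 0.903). At 10 months, replicate 3 correlated with replicates 1 and 2 at 0.924 and 0.931, and with the 5-month libraries at 0.87 and 0.879. Across harvests, 5-month replicate 2 and 10-month replicate 1 correlated at 0.933, slightly above those 2 pairs within the 10-month harvest. The first principal component (55.9% of the variance) set 2-month replicate 2 apart from the other 6 libraries. The second (18%) ran from the 5-month libraries to 10-month replicate 3, with the other 4 libraries between. The third (12.3%) set 2-month replicate 1 apart.

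**Figure D2:**
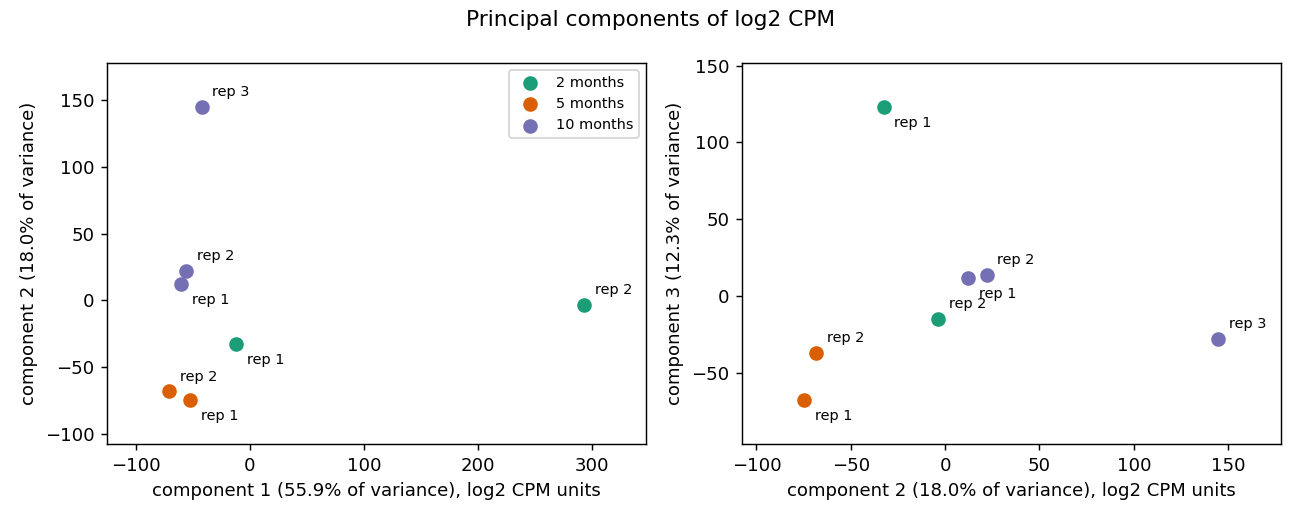
Libraries on the first 3 principal components of log2 CPM over 14753 gene models; axes give each component's score in log2 CPM units, and colours give the harvest. The 5-month libraries lie together, and 2-month replicate 2 lies alone at 293.1 on component 1.

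From 2 to 10 months, the longest interval, 346 of 14753 gene models changed, of which 242 rose and 104 fell. This balance depended on the fit: limma-voom with quality weights gave 174 rises and 178 falls, and a fit on these 2 harvests alone gave 12 rises and 20 falls. The changes that passed were large: the median absolute log2 fold change was 2.82, the smallest 1.40, and 91 gene models changed at least 16-fold. The largest rises among abundant models were in 430465 (1982 bp) and 424160 (825 bp). Gene model 430465 went from 0.201 ± 0.284 CPM (SD, n = 2) to 36.8 ± 37.2 CPM (SD, n = 3), with a log2 fold change of 7.01 (SE 1.13, edgeR adjusted p = 0.0184). Gene model 424160 went from 0.201 ± 0.284 to 27.0 ± 14.9 CPM, with a log2 fold change of 6.60 (SE 0.91, edgeR adjusted p = 0.0139). Each of these had 20 reads in 2-month replicate 1 and 0 in replicate 2, so the size of both rises, here and for 430465 from 2 to 5 months, rests on replicate 1. Without 10-month replicate 3 the log2 fold change of 430465 was 5.78. The largest falls were in 362799 (1957 bp), from 78.2 ± 41.1 to 0.432 ± 0.401 CPM (log2 fold change -7.44, SE 1.08, edgeR adjusted p = 0.0152), and in 415610 (1083 bp), from 71.5 ± 43.3 to 0.502 ± 0.502 CPM (log2 fold change -7.10, SE 1.05, edgeR adjusted p = 0.0152). At 5 months, 424160 stood at 2.55 ± 0.507 CPM, and 362799 and 415610 both had a mean of 5.03 CPM, between their values at the other harvests. The libraries of both harvests did not overlap in any of the 346 gene models. Over all tested models this held for 38.3%, against 20% by chance for groups of 2 and 3. Leaving out a 2-month or 5-month library leaves that harvest with 1 library, which is assumed to vary like the other groups, here and in the comparisons that follow. Without 2-month replicate 2, the library with the fewest gene models, 725 models changed and 293 of the 346 were among them. The count was 4943 without 2-month replicate 1, 151 and 110 without 5-month replicates 1 and 2, and 103, 33 and 150 without 10-month replicates 1, 2 and 3, and the falls of 362799 and 415610 did not pass without 10-month replicate 2, although their log2 fold changes were then -7.55 and -7.09. The log2 fold change of 362799 was -6.76 without 2-month replicate 2 and -8.20 without 10-month replicate 1, and that of 415610 was -6.27 without 2-month replicate 1 and -8.07 without 10-month replicate 1. The fit on these 2 harvests alone called none of the 4 named gene models, with log2 fold changes of 7.03, 6.61, -7.45 and -7.11, and limma-voom with quality weights did not call the rises of 430465 (5.88) and 424160 (6.12).

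From 2 to 5 months, 202 gene models changed, and 92 of them rose while 110 fell. The balance between rises and falls was not stable across fits. With median-of-ratios factors in edgeR 108 rose and 78 fell, and with the 8 abundant models left out 114 rose and 64 fell. With other tools, which also differ in filter or test, 881 rose and 394 fell (DESeq2) and 82 rose and 274 fell (limma-voom with quality weights). The median absolute log2 fold change of the 202 was 3.27, and 71 changed at least 16-fold. Gene model 512077 (1089 bp) was barely detected at 2 months, with 0 and 1 read, and stood at 49.8 ± 7.99 CPM (SD, n = 2) at 5 months (edgeR adjusted p = 0.00525). The pooled ratio was 3100, with an exact 95% counting interval of 556 to 122000. The log2 fold change of 512077 was 11.12 in the main fit, 8.81 without 2-month replicate 1 and 14.08 without 2-month replicate 2. Gene model 430465, which also led the rises to 10 months, was already at 26 ± 1.35 CPM at 5 months (log2 fold change 6.51, SE 1.13, edgeR adjusted p = 0.0309). Gene model 425196 (933 bp), one of the more abundant models at 2 months, fell from 4420 and 459 CPM in the 2-month libraries to 22.0 and 14.4 CPM (log2 fold change -7.07, SE 1.31, edgeR adjusted p = 0.0367). Gene model 438968 (1368 bp) fell from 31.8 ± 15.6 to 0.482 ± 0.367 CPM (log2 fold change -5.98, SE 1.15, edgeR adjusted p = 0.0414). None of the 202 overlapped between the libraries of both harvests, which held for 49.2% of tested models against 33.3% by chance for 2 and 2. Without 2-month replicate 2, 951 models changed, 199 of the 202 among them, and 3905 changed without 2-month replicate 1. The count fell to 84 and 58 without 10-month replicates 1 and 2, to 5 without 5-month replicate 1 and to 0 without 5-month replicate 2 (edgeR, 1204 at an unadjusted p under 0.05), where none of the 4 named calls held. The log2 fold changes of 512077, 430465, 425196 and 438968 without 5-month replicate 2 were 10.78, 6.48, -6.79 and -7.14, so they moved little or grew. Of those 4, the call of 512077 was the one kept without 5-month replicate 1. The call of 438968 was also lost without 10-month replicate 2 (-5.91), and that of 425196 without 10-month replicate 1 (-7.06) or 2 (-7.01). The log2 fold change of 425196 was -4.67 without 2-month replicate 1 and -7.88 without replicate 2, and that of 438968 was -5.35 without 2-month replicate 1 and -7.14 without 5-month replicate 2. In other fits some calls ended while the fold moved little: 425196 from these 2 harvests alone (-6.99), 438968 with the 8 abundant models left out (-5.70), and 430465 by limma-voom with quality weights (6.48).

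From 5 to 10 months, 272 gene models changed, and rises outnumbered falls, at 241 to 31. Gene models 425196 and 425708 (495 bp) had the largest rises. The former, which had fallen from 2 to 5 months, returned from 18.2 ± 5.41 CPM (SD, n = 2) to 1800 ± 1190 CPM (SD, n = 3), with a log2 fold change of 6.63 (SE 1.26, edgeR adjusted p = 0.0332). Gene model 425708 went from 23.3 ± 7.65 to 1660 ± 971 CPM (log2 fold change 6.15, SE 0.95, edgeR adjusted p = 0.0169), and had stood at 220.0 ± 183 CPM at 2 months. The largest falls were in 512077, from 49.8 ± 7.99 to 1.09 ± 0.517 CPM (log2 fold change -5.50, SE 0.63, edgeR adjusted p = 0.00988), and in 548530 (1488 bp), from 35.3 ± 17.1 to 2.92 ± 2.31 CPM (log2 fold change -3.59, SE 0.70, edgeR adjusted p = 0.0369). The median absolute log2 fold change was 2.49, and the libraries of both harvests did not overlap in any of the 272 models, which held for 48.8% of tested models against 20% by chance. With the 8 abundant models left out, 131 rose and 41 fell. Rises also outnumbered falls with DESeq2 (593 and 254) and with limma-voom with quality weights (1787 and 1111). Their share of the calls was smaller there, at 70% and 61.7%, against 88.6% in the main fit. The fit without 2-month replicate 2 and 10-month replicate 3, which leaves 1 library at 2 months, also called more rises than falls, at a smaller share. The count was 0 without 5-month replicate 1 or without 5-month replicate 2 (edgeR, 1019 and 1150 at an unadjusted p under 0.05), 76 and 8 without 10-month replicates 1 and 2, and 1475 and 1377 without 2-month replicates 1 and 2. Without 10-month replicate 2 none of the 4 named calls held, with log2 fold changes of 6.06, 5.97, -5.87 and -4.40, and without 10-month replicate 1 those of 425196 (6.53) and 548530 (-3.57) did not. The fall of 548530 also did not pass with the share of the 8 abundant models as a covariate, although its log2 fold change was then -3.53. It was -2.97 without 5-month replicate 1 and -4.40 without 10-month replicate 2.

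**Figure D3:**
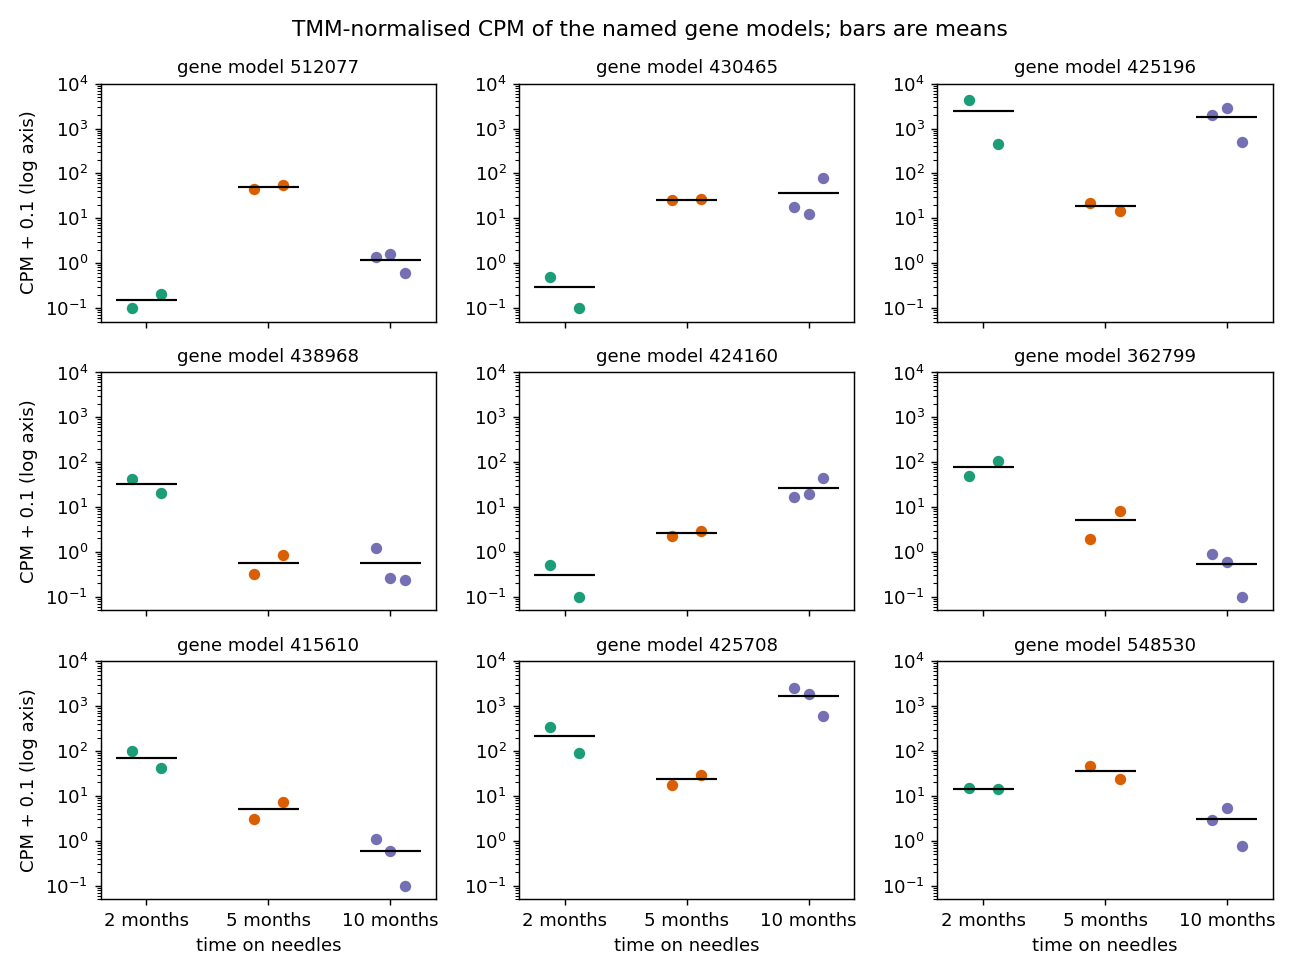
CPM (TMM-scaled) plus 0.1, on a log axis, of the 9 named gene models in each library against time on needles. Points are libraries and horizontal bars are means; 425196 is lowest and 512077 highest at 5 months, and 424160 rises from 0.201 to 2.55 to 27.0 CPM.

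Taking the harvests as 3 groups, 623 of 14753 gene models differed among them by the F test of edgeR. Of these, 368 (59.1%) had their highest mean at 10 months, against 32.8% of all tested models, 154 (24.7%, against 32.4%) at 2 months and 101 (16.2%, against 34.8%) at 5 months. The courses below, like the highest means above, come from the TMM scaling of the main fit only. The 10-month mean rests on 3 libraries and the others on 2, so a change at 10 months can pass more easily. In the simulated data, 8-fold changes at 10 months were called in 64.3% (against 2 months) and 66.7% (against 5 months) of cases. Those at 5 months (against 2 months) were called in 47.8%. The comparisons with all tested models do not allow for this. Most frequent was a lowest mean at 5 and a highest at 10 months, with 199 gene models (31.9%, against 14.2% of tested models). A further 169 (27.1%, against 18.5%) were lowest at 2 and highest at 10 months. Highest at 5 and lowest at 2 months were 90 (14.4%, against 24%), and highest at 2 and lowest at 5 months were 89 (14.3%, against 15%). The course highest at 5 and lowest at 10 months was taken by 11 (1.8%, against 10.9%). The course highest at 2 and lowest at 10 months was taken by 65 gene models (10.4%, against 17.4%), among them 362799 and 415610. Leaving out the most abundant gene models moved the median log2 fold change of all tested models. It went from 0.1 to 0.36 for 5 against 2 months and from -0.06 to -0.3 for 10 against 5 months. How far the courses depend on the scaling was not tested. Without 2-month replicate 2, 2012 gene models differed and 609 of the 623 were among them. The count was 5422 without 2-month replicate 1, 83 and 80 without 5-month replicates 1 and 2, and 240, 154 and 394 without 10-month replicates 1, 2 and 3. The common dispersion of the fit was 0.438, which is a biological coefficient of variation of 66.2%, pooled over the 3 harvests. It is not the spread of each harvest. Libraries of one harvest correlated at 0.806 at 2 months, 0.955 at 5 months and 0.924 to 0.972 at 10 months.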

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

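Unique reads, halved counts and the quality-weighted fit were among the alternatives chosen after seeing the data, as were the fits without the 8 most abundant models, with their share as a covariate and without both libraries in doubt (2-month replicate 2 and 10-month replicate 3). Counts below are given for 5 against 2, 10 against 2, 10 against 5 months and any time, where the main counts were 202, 346, 272 and 623. With library size in place of TMM they were 0, 0, 0 and 1 (edgeR, 584, 373, 85 and 292 at an unadjusted p under 0.05), and the median log2 fold change of all tested gene models moved from 0.10, 0.20 and -0.06 to 1.11, 0.60 and -0.62. With median-of-ratios factors these medians were 0.27, 0.21 and -0.22. With no low-count filter the counts were 583, 927, 697 and 1467, and with DESeq2 1275, 1811, 847 and 2097. The DESeq2 lists held all of the main calls (202, 346, 272 and 623). Fits on only the 2 harvests compared gave 95, 32 and 1520. Without both libraries in doubt 2994, 2236, 2638 and 4429 gene models were called, including 202, 345, 272 and 622 of the main calls, in fits that assume a lone library to vary like the other groups. The covariate gave 229 for 10 against 2 months, leaving out the 8 models gave 172 for 10 against 5 months, and limma-voom with quality weights gave 356 for 5 against 2 months (82 rose, 274 fell) and 2898 for 10 against 5 months. Leaving out 1 library gave 0 to 3905, 33 to 4943, 0 to 1475 and 80 to 5422. The cause of these shifts was not tested. The replicate block gave 113, 80, 117 and 281, and under it 438968 (5 against 2 months, log2 fold change -5.69) and 548530 (10 against 5 months, -3.11) were not called. Same-numbered libraries correlated in their deviations at -0.083 (2 and 5 months), at 0.039 and -0.021 (2 and 10 months) and at -0.222 and -0.032 (5 and 10 months). With so few libraries per harvest these values can barely test a pairing, and the numbers were not taken as pairing the samples. The remaining alternatives stayed within 1.5 times the main counts. The gap between correlations within and between harvests was 0.064 for all genes and 0.391 for the 1000 most variable genes, which are chosen to differ. For the 12 named results, 201 of 251 alternative values stayed past the threshold, 50 did not and 0 changed direction. The named results were chosen from these data for large folds and libraries without overlap, so a change of direction was unlikely from the start. Some alternatives, such as the fold minimum, could not end their calls. The alternatives on gene lists could not be run because no identifier has a name, and the pseudocount alternative applied to normalised files only. Depth limits low gene models most in 2-month replicate 2, where 2938002 reads lay outside the 8 abundant models.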

Other observations

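The tests in this part were chosen after the results they concern had been seen, except the thinning test and the length test. Among the 8 most abundant gene models, 358623 (426 bp) and 358649 (162 bp) varied 163.1-fold and 88.3-fold between libraries against all other reads. Gene models 391853, 500279, 434685, 358619 and 358617 varied 20.7-fold to 36.6-fold, and 348936 varied 6.3-fold. All but 348936 were highest in 2-month replicate 2 and next in 5-month replicate 1. The files hold no sequence, so whether these models stand for ribosomal RNA or for messenger RNA was not tested.

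Gene models that fell from 2 to 5 months had a median implied length of 1302 bp (110 models), against 1390 to 1770 bp in the central 95% of 10000 random sets matched on mean level (two-sided permutation test, p = 0.0038, adjusted p = 0.023 over 6 sets). That list is not stable, with 78 falls under median-of-ratios factors, 64 with the 8 abundant models left out, 274 by limma-voom with quality weights and 0 without 5-month replicate 2, and the length test was not run on those lists. Gene models that rose from 5 to 10 months had a median of 1420 bp (241 models, matched range 1425 to 1686 bp, adjusted p = 0.11). That is the smallest adjusted p of the 3 sets that rose, and whether harvest time changed long and short models alike among those that rose stays open. Genes are not independent replicates, so these values describe these libraries.

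The 2-month replicate 2 library had 9626 gene models at 0 reads, against 4650 in the other 2-month library. Fewer reads outside the 8 abundant models do not account for this alone, since at 2938002 such reads the lowest of the other 6 libraries still detected 12760 models against 10131. Harvest at 2 months stays open: at that depth 2-month replicate 1 detected 14053, more than 10-month replicate 3 (12760) but fewer than the other 4 later libraries (14497 to 16097). At equal reads, 5.05% of its detected gene models had 2 to 10 reads, against 20.9% in the lowest other library, a value that few starting RNA molecules, each read many times, could give. The same library had the highest share with exactly 1 read, 10.8% against 4.14% to 8.38% at equal reads, which that explanation alone does not give, so it stays open. RNA quality per library was not among the labels, and a biological difference of this microcosm stays open as untested.

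Even read numbers were in excess in every library. Among gene models with 2 to 20 reads, even numbers made up 67.1% to 79.5%, where equal use of all numbers would give 52.6%. The lowest value, 67.1%, lies above that, and a candidate explanation is that both mates of a pair were counted as separate reads, which would make the number of fragments about a factor of 2 lower than the reads. Halving the counts gave 211, 406 and 279 changed gene models for 5 against 2, 10 against 2 and 10 against 5 months.

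The 623 gene models that differed among harvests were tested against other splits of the 7 libraries into groups of 2, 2 and 3. Of the 100 splits run, 1 gave as many, the real one, and the highest of the others gave 27. This argues against a chance split, although 1 in 100 is the smallest share that this number of splits can give. Any other difference between the harvests, such as in handling, would also put the real split first, so the splits do not single out time. The libraries in the 3 next highest splits kept the 2-month pair together and moved one 10-month library to the 5-month pair. Without 2-month replicate 2, 609 of the 623 were still called, in a fit where the lone 2-month library is assumed to vary like the other groups. That fit called far more gene models than the main one, so it could hardly lose them and does not decide about that library. Leaving out 1 of the 5-month libraries, in contrast, lost most of the 623, and so did leaving out 10-month replicate 1 or 2. Without 10-month replicates 1, 2 and 3, 237, 154 and 347 of the 623 were still called. With the share of the 8 abundant models as a covariate, 461 of the 623 were still called, which argues against that share as the whole cause. Time on the needles stays a hypothesis beside differences between single microcosms, since each harvest is represented by 2 or 3 libraries.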
